A study of Mus musculus with 14 samples.

How the data were processed

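RNA of whole paws from 14 newborn mice was sequenced as ribosomal RNA-depleted total RNA. The deposited table gives raw read counts per gene for each library, as the authors made them, without normalization. The submitters' processing notes name STAR 2.7.10a, featureCounts, edgeR, limma and the GRCm39 build, and the filters and strand setting are not given in the sources used here. The values were checked to be whole numbers, and totals per library ran from 28947715 to 41004173. The table holds 56691 gene IDs, of which 52073 matched a symbol in the reference annotation used here. The other 4618 hold 0.623% of the counts and stayed in the fit under their IDs. Because that annotation is of another build than the authors' alignment, it served for names, gene order, distances to Krt9 and GC content, and no coordinates are given. No table column was without a sample.

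Samples were grouped by genotype and day per the labels, as P0 WT (n = 4), P0 Krt9 null (n = 2), P3 WT (n = 5) and P3 Krt9 null (n = 3). Genes were kept by edgeR's filterByExpr (21619 of 56691), scaled by TMM, and fitted with edgeR 4.0.16 quasi-likelihood with robust dispersions in R 4.3.3, with all 14 libraries in 1 fit of the 4 groups and labelled sex as a covariate, which left 9 residual degrees of freedom. The 6 contrasts tested were genotype on each day, day in each genotype, their interaction, and genotype averaged over the days. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Folds and log2 fold changes are fitted values, SE is their standard error, and CPM values are means of the libraries after TMM scaling. A total of 53 gene lists was fixed, and the 52 with at least 3 members past the filter were tested by camera of limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera called 26 lists for genotype on P0, 26 on P3, 25 for day in WT, 30 for day in Krt9 null paws, 20 for the interaction and 21 for the averaged genotype effect. Lists were described by their calls over all genes and by calls adjusted over the list alone. Median, mean and camera direction had the same sign in every called list. Marker scores were means of log2(CPM + 1), compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over the 52 lists of a comparison. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.

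Named genes were Krt9 and, for each contrast, up to 8 higher and 8 lower genes with the largest log2 fold change among those called, with a mean of at least 2 CPM in the higher group and no overlap of the libraries compared (up to 5 each way and no overlap rule for the interaction), leaving out predicted genes and clones. The basal, stress and differentiation keratins were named in the genotype contrasts, and each described list was represented by up to 3 called members with the smallest adjusted p or, where none was called, by up to 2 members with the highest mean CPM. Groups, tests, lists, this rule and the alternatives listed first below were set before the data were examined. Krt7, Krt8 and Krt18, the collagen ratio, the keratins named for the WT day comparison other than Krt9, Krt40, Krt6b and the hair keratins, and the genes called only with the block term were named after their values were seen. Some genes that the rule reaches were left out of the text because they are withheld for evaluation.

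The alternatives were other scaling (DESeq2 size factors, library size only, abundant RNA classes removed), no filter or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, dispersions that were not robust, no sex term, an epithelial score as covariate, only the groups compared, litter as a block, the 2 males of P3 WT litter 2 summed, a pseudocount of 0.25 in the scores, only genes of at least 5 CPM in the comparisons across genes, windows of 5 and 20 Mb around Krt9, and leaving out each library in turn. Further ones, chosen after seeing the data, were the column block as a term, also as a term within each day, each block alone, a GC offset per library, and the block term without WT replicate 4 of P0. Scores of the cornified envelope and basal keratins were also fitted per library by least squares on group, sex and the block terms, after the data were seen. The column block is inferred from column names, not from a stated batch. The number after the day in the sample titles was read as a litter number, and such numbers recur on both days. Whether it stands for a litter, and whether equal numbers mean 1 litter, is not given in the sources used here. Libraries of equal litter number on both days or within P0 had residual correlations between -0.17 and 0.23 and in no such pair was the partner the closest library of the first. The consensus correlation was 0.555 for litters within a day and -0.054 across days. Within a day, only replicates 1 of Krt9 null and WT on P0, and WT replicates 2 and 3 on P3, share a number. All of these lie in block A, so the value within a day cannot tell litter from block.

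The fit was tested on simulated data with 50 genes changed at each of 4 folds. The changed genes were planted all at once among genes above a low-level cut, with independent genes and no column block. Where few genes truly change, as may hold for the genotype contrasts, recovery can be lower. At 4-fold it recovered 84% of them for genotype on P0, 88% on P3, 94% for day in WT, 92% for day in Krt9 null paws, 76% for the interaction and 96% for the average. At 2-fold it recovered 38%, 56%, 64%, 40%, 12% and 80%, with between 4 and 11 false calls in each contrast. At 1.5-fold it recovered 6%, 6%, 24%, 4%, 0% and 42%, and at 0.25-fold 78%, 88%, 84%, 86%, 64% and 100%, in the same order. A simulated list of 26 genes changed 1.5-fold had camera adjusted p = 2.06e-22, and 0 of 50 random lists were called, in simulated data without correlated genes. No pair of libraries of the same group was a duplicate by its counts.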

Results

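The series profiled RNA of whole paws of newborn mice labelled wild type or null for Krt9, the keratin of palm and sole epidermis, on postnatal day 0 (P0) and day 3 (P3). Ribosomal RNA was depleted from total RNA, and reads of 14 libraries were counted per gene. Wild-type (WT) paws gave 4 libraries on P0 and 5 on P3, and Krt9 null paws gave 2 on P0 and 3 on P3. Each library held between 28947715 and 41004173 counts and between 25119 and 28061 genes with at least 1 count. Type I collagen Col1a1 took the largest share of counts in 9 libraries, and the suprabasal keratin Krt1 did so in 2 of the 3 Krt9 null paws of P3. On the first principal component, which held 50.8% of the variance of the 1000 most variable genes, all P0 libraries lay between -43.3 and -20.8 and all P3 libraries between 1.10 and 54.6.

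The deposited columns form 2 alphabetical runs, called block A (8 libraries) and block B (6 libraries) here, that cut across the 4 groups. The log2 ratio of Col1a1 to Col1a2, the partner chains of type I collagen, lay between 0.33 and 0.46 in block A and between -0.13 and 0.08 in block B. The slope of log2 CPM (normalised read counts scaled to the library total) on the GC fraction of transcripts was 1.12 ± 0.391 (SD, n = 8) in block A and -1.49 ± 0.451 (SD, n = 6) in block B. For each measure the exact two-sided permutation p was 0.000333, the smallest that the 3003 splits can give. As a term in the fit, the block had 5017 genes past the threshold, so values within each block stand beside the lists and a part of the genes below. On P0 block B held 1 Krt9 null and 1 WT library, and on P3 block A held 1 Krt9 null library against 3 WT. The Krt9 null paws of P3 in which Krt1 took the largest share (replicates 1 and 3) were of block B. In every block A library Col1a1 took the largest share. WT replicate 4 of P0 is labelled female but held 0.181 CPM of Xist, transcribed from the inactive X chromosome, and 0.155 CPM of the Y-linked Ddx3y. The sex markers of the other 13 libraries matched their labels.

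**Figure D1:**
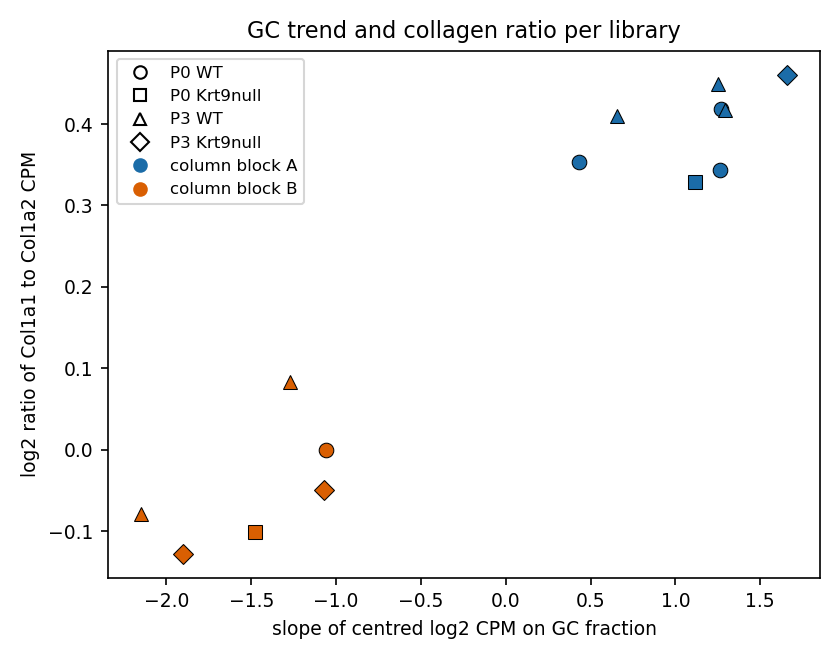
Slope of centred log2 CPM on the GC fraction of transcripts (x axis, log2 CPM per unit of GC fraction) against the log2 ratio of Col1a1 to Col1a2 CPM (y axis), 1 point per library, with color for the column block and shape for the group. The 8 block A libraries lie between 0.33 and 0.46 in the collagen ratio and the 6 block B libraries between -0.13 and 0.08, with all 4 groups present in both.

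The first question was how the targeted gene itself behaved. Krt9 (ENSMUSG00000051617.4) increased in WT paws from 4.97 ± 2.29 CPM (SD, n = 4) on P0 to 53.9 ± 22.9 CPM (n = 5) on P3, a log2 fold change of 3.42 (SE 0.48, 10.7-fold, edgeR's adjusted p = 0.00154). In Krt9 null paws Krt9 was at 5.70 ± 0.543 CPM (n = 2) on P0 and at 14.8 ± 9.16 CPM (n = 3) on P3. The Krt9 null paws of P3 held 25.2, 7.74 and 11.5 CPM of Krt9, and each was below the lowest WT paw of that day, at 32.9 CPM. The genotype log2 fold change of Krt9 was 0.19 (SE 0.56) on P0 and -1.86 (SE 0.49) on P3, with edgeR's adjusted p = 0.968 and 0.694, so neither passed over all genes tested. The labels do not give the type of allele, and on P0 both Krt9 null libraries (6.09 and 5.32 CPM) lay within the WT range of Krt9 RNA (2.09 to 7.61 CPM). DESeq2 called the P3 difference at -1.86 with adjusted p = 0.0124. Within blocks, the P3 difference of Krt9 was -3.08 in block A and -0.98 in block B. The P0 difference was 0.37 and -0.06, and the WT day difference was 3.84 and 2.71, the last not called in block B alone.

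The gene that separated the genotypes on both days was Krt19 (ENSMUSG00000020911.15), a type I keratin of simple epithelia and hair follicle bulge cells. Krt19 was at 1.39 ± 0.198 CPM (SD, n = 4) in WT and 154 ± 77.4 CPM (n = 2) in Krt9 null paws on P0. On P3 it was at 1.29 ± 0.532 CPM (n = 5) and 69.7 ± 21.7 CPM (n = 3). It rose 109-fold on P0 (log2 6.77, SE 0.39, edgeR's adjusted p = 5.17e-06) and 51.2-fold on P3 (log2 5.68, SE 0.34, edgeR's adjusted p = 9.20e-06). The Krt19 difference held in both blocks, at log2 6.17 in block A and 7.21 in block B on P0, and 5.71 and 5.72 on P3, but did not pass in block B alone or with litter as a fixed term. The other simple epithelial keratins did not pass the test. On P3 Krt7 was at 53.1 ± 11.8 CPM in WT and 69.6 ± 15.7 CPM in Krt9 null paws (n = 5 and 3). Krt8 was at 7.23 ± 2.87 and 8.39 ± 1.32 CPM, and Krt18 at 3.38 ± 1.58 and 3.55 ± 1.13 CPM. In gene order Krt19 is the nearest tested neighbour of Krt9 on 1 side and Krt14 the nearest on the other. Among the 8 tested neighbours on each side of Krt9, Krt19 alone was called on either day. Of 426 tested genes within 10 Mb of Krt9, 1 was called on each day, against 0 of 20704 elsewhere, and that gene was Krt19. Genes with an unadjusted p under 0.05 made up 5.63% of those near Krt9 and 6.0% of the rest on P0, and 7.28% and 6.67% on P3.

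**Figure D2:**
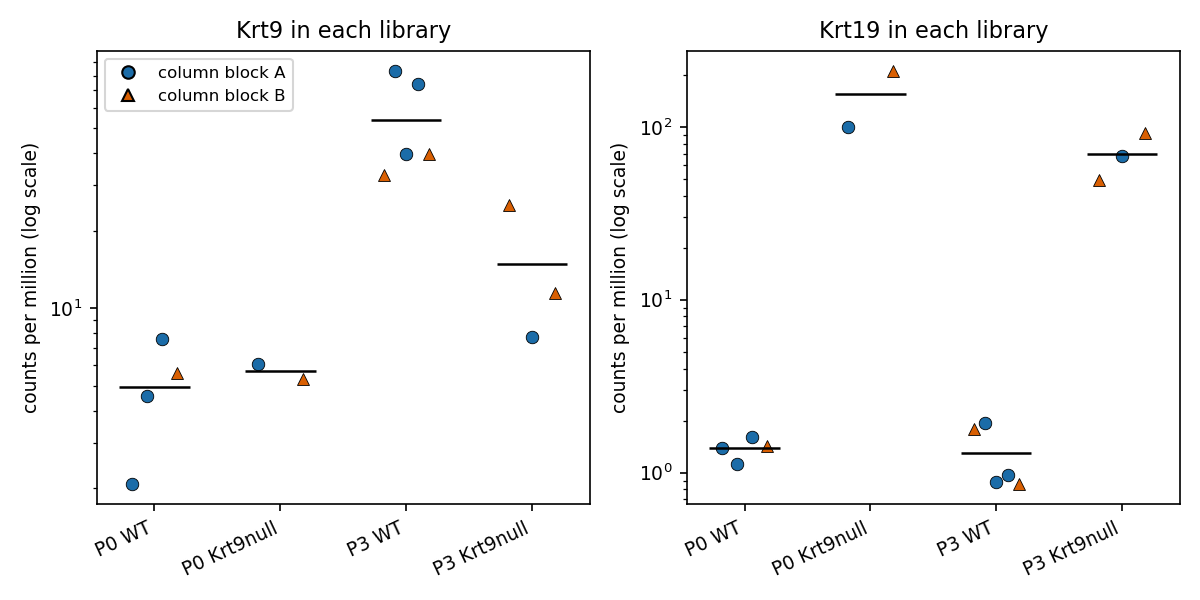
Krt9 (left) and Krt19 (right) in each of the 14 libraries, in CPM on a log scale, by group, with horizontal lines at the group means and color and shape for the column block. Krt9 null paws hold between 48.9 and 209 CPM of Krt19 and WT paws between 0.865 and 1.95, while Krt9 lies between 7.74 and 25.2 CPM in Krt9 null and between 32.9 and 83.0 CPM in WT paws of P3.

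At birth (P0, 2 Krt9 null against 4 WT paws), Krt19 was the 1 gene past the threshold, and genes of the differentiated epidermal layers had lower medians in Krt9 null paws. Of 26 genes of the cornified envelope, the protein shell of dead surface keratinocytes, none was called over all genes and 1 was lower when adjusted over the list alone. Their median log2 fold change was -0.51 and camera gave adjusted p = 8.26e-07, against adjusted p = 0.572 with an estimated correlation. Loricrin (Lor), its main protein, was at 8366 ± 3033 CPM (SD, n = 4) in WT and 4205 ± 1015 CPM (n = 2) in Krt9 null paws. The filaggrin protease Asprv1 was at 2758 ± 951 and 1904 ± 174 CPM. The 22 genes of barrier lipids had a median of -0.51, with 0 called over all genes or adjusted over the list alone (camera adjusted p = 7.99e-05, and adjusted p = 0.572 with an estimated correlation). The fatty acid elongases Elovl1, at 384 ± 119 CPM in WT and 257 ± 20.4 CPM in Krt9 null paws, and Elovl4, at 321 ± 104 and 222 ± 27.7 CPM, belong to it. The cornified envelope score was 7.79 and 7.50 in the Krt9 null libraries and 8.21 to 8.49 in WT replicates 1 to 3, but 7.22 in WT replicate 4. With the epithelial score as a covariate, the medians of the 2 lists were -0.088 and -0.078 and the calls ended (camera adjusted p = 0.139 and 0.0981). Without WT replicate 2 the barrier lipid median was -0.29, and without Krt9 null replicate 1 it was -0.40 and no longer called by camera. The suprabasal pair Krt1 and Krt10 had log2 fold changes of -0.92 (SE 0.36) and -0.97 (SE 0.40), and the wound-response keratins Krt6a, Krt6b and Krt16 had -1.45, -1.40 and -1.60, while the basal pair Krt5 and Krt14 had -0.19 and -0.37. Krt6a, Krt6b and Krt16 had -1.49, -1.73 and -2.26 in block A but 0.97, 1.85 and 0.56 in block B. Krt2, Krt5, Krt14, Krt17, Krt23, Krt24, Krt77 and Krt78 differed in direction between the blocks as well. None of these keratins passed, nor did Krt2, Krt15, Krt17, Krt23, Krt24, Krt75, Krt77, Krt78, Krt79 and Krt80, at -0.74 to 1.22.

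Outside the barrier genes, the 20 genes of cholesterol synthesis had a median log2 fold change of -0.42 on P0. Among them, Hmgcs1 was at 160 ± 40.8 CPM in WT and 119 ± 26.3 CPM in Krt9 null paws (SD, n = 4 and 2). Mature fast muscle genes had a median of -0.76 over 17 genes, with the fast myosin light chain Mylpf at 810 ± 416 and 545 ± 162 CPM. Osteoclast genes had a median of -0.50 over 10 genes, with the bone-resorbing protease Ctsk at 588 ± 160 and 428 ± 11.8 CPM. The 21 genes of the interferon response had a median of 0.50, with the transcription factor Irf9 at 30.3 ± 5.93 and 38.3 ± 12.3 CPM. Camera called each of these 4 lists, with adjusted p between 2.57e-07 and 0.000147 (cholesterol synthesis and osteoclast), and each had adjusted p = 0.572 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Without WT replicate 2 the fast muscle median was -0.33 and that of cholesterol synthesis -0.21. The fast muscle score of that library was 6.57, and those of the other 3 WT libraries of P0 were 4.56 to 5.38. The medians of osteoclast and interferon response genes were -0.12 and 0.11 without Krt9 null replicate 2, where neither was called, and without Krt9 null replicate 1 the osteoclast median was -0.95. Within block A the medians were -0.61 for the cornified envelope, -0.64 for barrier lipids, -0.38 for cholesterol synthesis, -1.07 for fast muscle, -0.31 for osteoclast and 0.29 for interferon response genes. Within block B, with 1 library per genotype, they were 0.29, 0.26, -0.02, -0.44, -0.72 and 0.22, so the 2 barrier lists pointed the other way there. Beside the 1 call by edgeR, 1289 of 21619 genes had an unadjusted p under 0.05, and DESeq2 called 9 genes. Chance alone gives a share of 0.05 of the genes tested, and away from Krt9 the share was 6.0%, little above it. With the block as a term and without WT replicate 4, an alternative chosen after seeing the data, 1251 genes passed, 560 higher and 691 lower, Krt23 and Krt6a among the lower, and the cornified envelope had a median of -0.98. That fit left block B no WT library on P0, so these calls rest on a block effect taken as equal on both days. With the block as a term within each day and all libraries, 2 genes passed on P0. Without WT replicate 4 alone, 3 genes passed.

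On P3 (3 Krt9 null against 5 WT paws), Krt19 was again the 1 gene past the threshold, and the same epidermal gene groups had higher medians in Krt9 null paws. Adjusted over the list alone, 19 of 26 cornified envelope genes, 15 of 22 barrier lipid genes, 12 of 20 genes of the late cornified envelope family and 6 of 9 differentiation keratins were higher and none was lower, while 0 passed over all genes tested. With the block as a term these counts were 5, 3, 0 and 0, while the medians were 0.84, 0.85, 0.82 and 0.82 and camera still called the 4 lists, which had adjusted p = 0.222, 0.222, 0.334 and 0.210 with an estimated correlation. Lor was at 4060 ± 660 CPM (SD, n = 5) in WT and 6934 ± 1735 CPM (n = 3) in Krt9 null paws, a log2 fold change of 0.89 (SE 0.19). Krt1 was at 7836 ± 1742 and 14070 ± 6349 CPM (log2 0.93, SE 0.29), and Krt10 at 6616 ± 1746 and 11520 ± 5555 CPM (log2 0.89, SE 0.32). Asprv1 had a log2 fold change of 1.04, Elovl1 1.01, Elovl4 0.98, and the envelope genes Lce1m and Lce1a1 0.70 and 0.80. The medians were 0.89 for the cornified envelope, 0.96 for barrier lipids, 0.85 for the late cornified envelope family and 0.93 for the differentiation keratins, with camera adjusted p = 2.01e-29, 9.91e-21, 8.10e-16 and 1.90e-09. They had adjusted p = 0.155, 0.160, 0.231 and 0.155 with an estimated correlation. Within block B the 4 medians were 0.85, 0.84, 0.86 and 0.83, and within block A, with its 1 Krt9 null library, 0.02, 0.00, 0.09 and 0.07, so the P3 difference did not hold within block A. General epithelial markers, such as E-cadherin (Cdh1, at 174 ± 22.8 and 226 ± 55.6 CPM), lay higher as well, with a median of 0.48 over 14 genes, 0.05 in block A and 0.34 in block B. None passed even adjusted over the list alone, and camera gave adjusted p = 7.32e-11, against adjusted p = 0.155 with an estimated correlation. With the epithelial score as a covariate, the cornified envelope, late cornified envelope and barrier lipid medians turned to -0.11, -0.12 and -0.076, and that of the differentiation keratins was 0.072. Without Krt9 null replicate 3 the late cornified envelope median was 0.48 and that of the differentiation keratins 0.60, both still called.

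Single keratins of P3 had genotype log2 fold changes of 1.18 (SE 0.33) for Krt2, 1.03 (SE 0.31) for Krt78, 1.07 for Krt77, 1.00 for Krt23, 0.64 for Krt80, 0.27 for Krt24 and 0.13 for Krt79. The basal keratins Krt5, Krt14 and Krt15 had 0.22, 0.04 and -0.50, and the stress keratins Krt6a, Krt6b, Krt16, Krt17 and Krt75 had 0.88, 1.99, 0.42, -0.18 and 0.51. In blocks A and B alone the direction differed for Krt6b (-0.67 and 1.87), Krt16 (-1.83 and 0.59), Krt75 (0.82 and -0.37), Krt14 (-0.25 and 0.14) and Krt79 (0.26 and -0.16). It also differed for Krt5, Krt10, Krt23 and Krt24, with values between -0.08 and 0 in block A. None of these keratins passed over all genes, with edgeR's adjusted p between 0.694 and 0.992. The 20 genes of cholesterol synthesis had a median of 0.51, 13 of them higher when adjusted over the list alone and 0 over all genes. Hmgcs1 was at 166 ± 24.4 CPM in WT and 234 ± 52.9 CPM in Krt9 null paws (SD, n = 5 and 3). Interferon response genes had a median of -0.62 over 21 genes, with Bst2, which tethers virus particles, at 22.8 ± 4.73 and 15.8 ± 1.36 CPM and no member past the test adjusted over the list alone. Osteoclast genes had a median of -0.77 with 4 of 10 lower when adjusted over the list alone (Ctsk at 735 ± 98.4 and 455 ± 141 CPM). Endothelial genes had a median of -0.40 with 3 of 16 lower (Pecam1 at 137 ± 14.7 and 99.4 ± 27.4 CPM). Camera gave these 4 lists adjusted p = 6.58e-16, 1.84e-10, 5.60e-10 and 3.69e-08, and they had adjusted p = 0.155, 0.231, 0.219 and 0.219 with an estimated correlation. Their medians were 0.19, -0.76, -0.21 and -0.07 in block A and 0.53, -0.44, -0.92 and -0.39 in block B. With the epithelial score as a covariate, 3 of these calls ended, for cholesterol synthesis (0.076, camera adjusted p = 0.101), osteoclast (-0.37, adjusted p = 0.0574) and endothelial genes (-0.05, adjusted p = 0.380). The interferon call stayed (-0.40, camera adjusted p = 0.00932). The interferon median was -1.07 and the endothelial one -0.20 without Krt9 null replicate 1. Without Krt9 null replicate 2 osteoclast genes had -1.20 and endothelial genes -0.65, and without WT replicate 4 endothelial genes had -0.26. By edgeR 1442 of 21619 genes had an unadjusted p under 0.05, and DESeq2 called 26 genes. Away from Krt9 the share of such genes was 6.67%, where chance alone gives a share of 0.05. With the block as a term, chosen after seeing the data, 7 genes passed, which were Krt19, Spp1 and the higher Tmem79, Plekhn1, Ppp1r13l, Camsap3 and Hspa1a. With the block term and without WT replicate 4 of P0, 55 passed. Without Krt9 null replicate 2, the block A library, 200 passed, and without WT replicate 4 of P0 alone 2 passed.

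**Figure D3:**
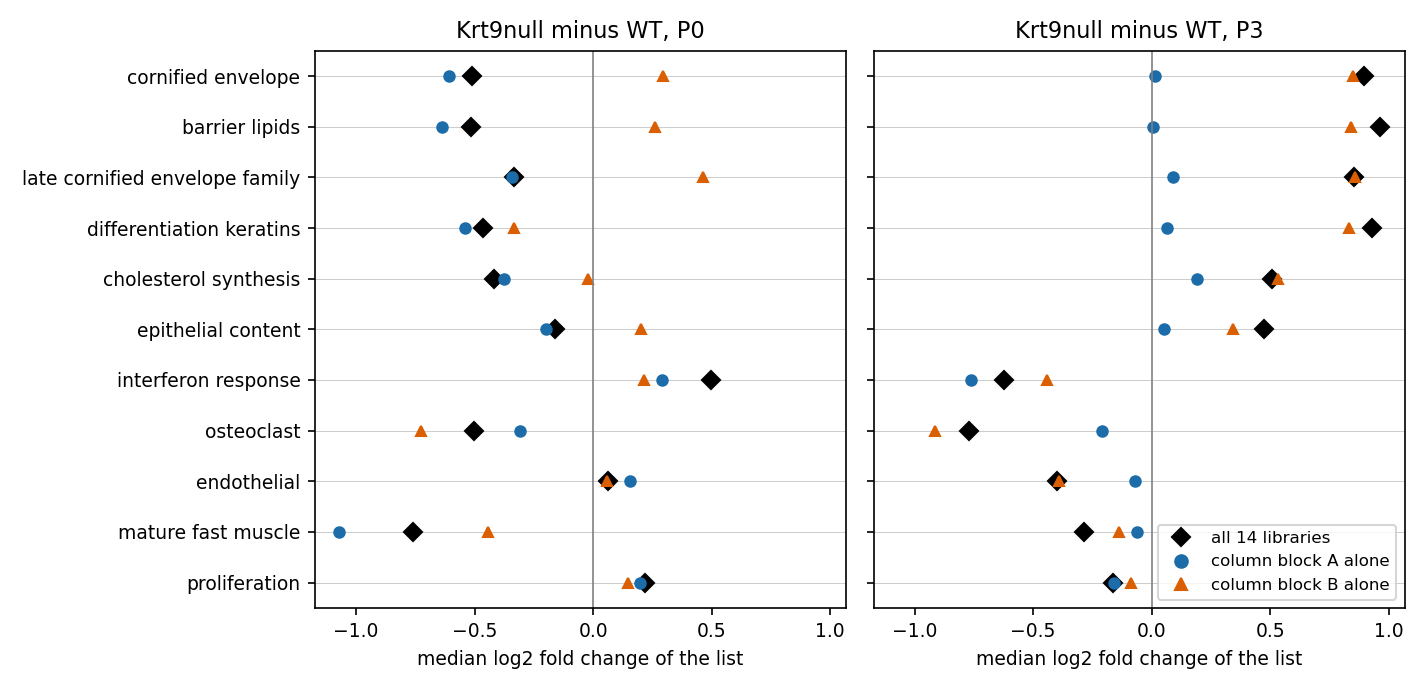
Median log2 fold change (x axis) of Krt9 null against WT paws for 11 gene lists on P0 (left) and P3 (right), from all 14 libraries (diamonds), block A alone (circles) and block B alone (triangles). The cornified envelope median is -0.51 on P0 and 0.89 on P3, with 0.29 on P0 in block B and 0.02 on P3 in block A.

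The change of the genotype effect between the days was tested as an interaction, P3 effect minus P0 effect. Cornified envelope genes had a median interaction of 1.48, with Lor at 1.86 (SE 0.30, edgeR's adjusted p = 0.119), as WT paws went from 8366 to 4060 CPM of Lor and Krt9 null paws from 4205 to 6934. Barrier lipid genes had a median of 1.49, differentiation keratins 1.38 with Krt1 at 1.85 and Krt10 at 1.86, and cholesterol synthesis 0.93 with Hmgcs1 at 1.00 (SE 0.29). Adjusted over the list alone, 11 of 26 envelope genes, 8 of 22 barrier lipid genes, 5 of 9 differentiation keratins, 16 of 20 cholesterol genes and 2 of 14 epithelial markers (median 0.60) were positive. Of 21 interferon genes (median -1.16) 0 passed. Camera gave these 6 lists adjusted p between 2.52e-26 (cornified envelope) and 2.10e-07 (differentiation keratins). They had adjusted p = 0.221 (differentiation keratins and cholesterol synthesis) or 0.246 (the other 4) with an estimated correlation. In block A and block B alone the medians were 0.65 and 0.57 for the cornified envelope, 0.69 and 0.60 for barrier lipids, and 0.61 and 0.88 for differentiation keratins. They were 0.60 and 0.55 for cholesterol synthesis, -0.80 and -0.69 for interferon and 0.22 and 0.21 for epithelial marker genes. With the epithelial score as a covariate, the medians were -0.17 for the cornified envelope, -0.06 for barrier lipids and 0.44 for differentiation keratins. Their calls ended (camera adjusted p = 0.817, 0.680 and 0.124). The epithelial markers (-0.12, camera adjusted p = 0.990) are no test here, as the covariate is the mean of that same list. Cholesterol synthesis (0.29, camera adjusted p = 0.000667) and interferon genes (-0.78, adjusted p = 9.00e-05) were still called. The interaction of Krt9 was -2.05 (SE 0.72, edgeR's adjusted p = 0.583; -3.45 in block A and -0.92 in block B) and that of Krt19 -1.09 (SE 0.49, edgeR's adjusted p = 0.644; -0.46 and -1.49), the latter -0.30 without Krt9 null replicate 2 of P0. Over all 21619 genes edgeR's interaction test called 0, with 1644 genes at an unadjusted p under 0.05, where chance alone gives a share of 0.05. DESeq2 called 85 and limma voom 0. With the block as a term 7 genes passed, all positive, among them Tmem79, Lor, Crybg2, Ppp1r13l and Evpl, and 1491 passed with the block term and without WT replicate 4 of P0. The count of 1491 rests on a block effect taken as equal on both days, as block B then held no WT library of P0. Lor and Evpl are envelope proteins. Without WT replicate 4 of P0 alone 47 genes passed, and without Krt9 null replicate 2 of P3 13 passed.

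Averaged over both days (5 Krt9 null against 9 WT paws), Krt19 rose 74.7-fold (log2 6.22, SE 0.26, edgeR's adjusted p = 1.08e-07). Spp1 (ENSMUSG00000029304.15), which encodes the bone matrix protein osteopontin, fell (log2 -0.82, SE 0.11, edgeR's adjusted p = 0.0417). Spp1 was at 1999 ± 402 CPM (SD, n = 4) in WT and 1084 ± 325 CPM (n = 2) in Krt9 null paws on P0. On P3 it was at 1412 ± 206 CPM (n = 5) and 911 ± 149 CPM (n = 3). The averaged Spp1 difference was -0.74 in block A and -0.83 in block B, and it was called again with the block term (-0.83, edgeR's adjusted p = 0.00223). Genes of 3 skeletal lists lay lower, without single calls other than Spp1. By mean scores per library, a different measure, chondrocyte genes differed by -0.07 on P0 and -0.03 on P3. The SDs of these scores in Krt9 null and WT paws were 1.052 and 1.005 on P0 and 0.0928 and 0.906 on P3. A shift of the size of the other lists could therefore be missed. The mean scores of tendon and joint genes differed by -0.03 and -0.21. Osteoclast genes had a median of -0.77 (4 of 10 lower adjusted over the list alone, with Mmp9 at -0.90), and osteoblast and osteocyte genes -0.59 (0 of 15, with Ibsp at -0.81). Hypertrophic cartilage genes had -0.42 (4 of 9 lower adjusted over the list alone, Spp1 the 1 over all genes). Camera adjusted p = 1.24e-13, 3.54e-10 and 5.50e-08 for these 3 lists became adjusted p = 0.344, 0.448 and 0.344 with an estimated correlation. Their medians were -0.37, -0.13 and -0.08 in block A and -0.87, -0.96 and -0.96 in block B. Without Krt9 null replicate 1 of P0 or replicate 2 of P3, osteoblast and osteocyte genes had -0.92 and -0.97 and hypertrophic cartilage genes -0.81 and -0.67. Without Krt9 null replicate 2 of P0 osteoblast and osteocyte genes had -0.37. Simple epithelial keratins, 5 genes with Krt19 as the 1 call and a median of 0.20, were the list that was called with an estimated correlation, at adjusted p = 0.0286 on P0, 0.0109 on P3 and 0.00110 in the average. With the block term they had adjusted p = 0.0836, 0.0540 and 0.00461 with an estimated correlation, so the calls on the single days ended. Without Krt19 the list had no member past the threshold. The call of Spp1 ended in 18 of the alternatives, among them 11 of the 14 fits without 1 library, where its log2 fold change stayed between -0.89 and -0.74. By edgeR 963 genes had an unadjusted p under 0.05 in the average. Away from Krt9 their share was 4.47%, below the share of 0.05 that chance alone gives.

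In WT paws (5 of P3 against 4 of P0), the first days after birth changed 3581 genes, 1836 higher and 1745 lower on P3. Pigment cell genes rose, with 7 of 9 melanocyte genes higher: the melanin enzyme Tyr went from 1.97 ± 0.246 to 7.82 ± 1.73 CPM (SD, n = 4 and 5), Tyrp1 rose 12.6-fold and Dct 2.95-fold. Hair and nail keratins rose in 10 of 20 genes, among them the inner root sheath keratins Krt28 (17.2-fold), Krt73 (22.6-fold) and Krt71, which went from 17.3 ± 14.4 to 355 ± 266 CPM. Of 17 adipocyte genes, 7 rose, with the lipid droplet genes Plin1 (35.1-fold, from 0.196 ± 0.284 to 6.02 ± 2.38 CPM) and Cidec (26.1-fold) and the glyceroneogenic enzyme Pck1 (9.29-fold) ahead. Proliferation genes rose in 15 of 21, with smaller folds, as in Top2a (1.63-fold), Bub1b (1.70-fold) and the replication helicase subunit Mcm5 (1.95-fold). Macrophage genes rose in 11 of 16, with Adgre1 2.32-fold, Lyz2 4.09-fold and Ms4a7 2.01-fold higher. None of the members of these 5 lists fell over all genes tested. The adipocyte median of 0.75 was 1.32 without Krt9 null replicate 1 or 3 of P3.

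In the same comparison, muscle, basement membrane and small proline-rich genes fell. Of 14 embryonic and neonatal muscle genes 10 fell, with the embryonic troponin Tnnt2 at 74.6 ± 11.3 CPM on P0 and 22.9 ± 5.47 CPM on P3 (SD, n = 4 and 5). The myogenic factor Myog was at 54.8 ± 13.7 and 13.4 ± 6.62 CPM, and Myl4 at 127 ± 28.2 and 51.1 ± 17.8 CPM. Slow muscle genes fell in 6 of 9, as in Myl3 (log2 -1.85), Tnnt1 (-1.24) and Tnnc1 (-1.44). The small proline-rich family, envelope precursors of stressed and fetal epidermis, fell in 10 of 14, with Sprr2d at 68.7 ± 43.9 and 1.21 ± 0.554 CPM, while Sprr4 rose 39.0-fold. Of 15 hemidesmosome and basement membrane genes 10 fell and 1 rose, with the linker protein Dst at 601 ± 91.2 and 327 ± 58.0 CPM and the integrin chain Itga3 at 83.6 ± 25.5 and 39.3 ± 9.40 CPM. Of 22 immediate early genes 14 fell, with Zfp36 at log2 -1.04, Fosl1 at -3.71 and Junb at -0.94. Of 5 stress keratins 3 fell, Krt6a at log2 -3.40, Krt6b at -4.97 and Krt16 at -4.17, and Krt75 rose at log2 3.28. The list was not called (camera adjusted p = 0.0661), with a median of -3.83 in block A and -0.37 in block B. Krt2 rose 25-fold from 4.01 ± 1.73 to 110 ± 33.3 CPM (SE 0.38 in log2, edgeR's adjusted p = 0.000241).

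By the rule for single genes, the rises in WT paws were largest for the hair keratin-associated Krtap5-5 (0.0325 ± 0.0389 to 5.91 ± 8.37 CPM, SD, n = 4 and 5), Actbl2 (44.4-fold), Sprr4, Calhm4 (35.9-fold), the hair keratin Krt40 (35.8-fold), Plin1, the lysozyme-like Lyg2 (26.6-fold) and Cidec. The falls were largest for the envelope gene Lce3d (28 ± 21.4 to 0.221 ± 0.143 CPM, 129-fold lower), Sprr2e (57.3-fold lower) and the neuropeptide precursor Calca (56.7-fold lower, 11.8 ± 4.79 to 0.192 ± 0.148 CPM). They were followed by Sprr2d, Sprr2g (48.7-fold lower), Krt6b, Lce3f (24.0-fold lower) and the peroxidase Lpo (23.6-fold lower). All 16 had edgeR's adjusted p between 0.000637 (Lce3f) and 0.0332 (Lyg2). In block A and block B alone, with 3 P0 and 3 P3 libraries in A and 1 and 2 in B, log2 fold changes were 5.28 and 4.65 for Plin1, -5.28 and -7.89 for Calca, -5.39 and -1.77 for Lce3f, and -5.84 and -1.07 for Krt6b. The list medians in blocks A and B were 1.82 and 1.84 for melanocyte, 2.78 and 2.79 for hair and nail keratin, 0.96 and 1.37 for adipocyte, 0.61 and 0.25 for proliferation and 0.87 and 0.35 for macrophage genes. They were -1.21 and -1.54 for embryonic muscle, -1.24 and -1.29 for slow muscle, -3.66 and -1.26 for small proline-rich and -0.52 and -0.63 for basement membrane genes. Immediate early genes had -1.07 in block A and 0.18 in block B, so their fall did not hold in block B.

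Camera called the 10 lists named for the WT day comparison, with adjusted p between 7.28e-12 (proliferation) and 2.42e-06 (adipocyte), and they had adjusted p between 0.177 and 0.395 with an estimated correlation. Adjusted over the list alone, the counts were 7 of 9 higher for melanocyte, 11 of 20 for hair and nail keratins, 9 of 17 for adipocyte with 1 lower, 19 of 21 for proliferation and 13 of 16 for macrophage genes with 1 lower. For the falling lists they were 13 of 14 lower for embryonic muscle, 8 of 9 for slow muscle, 11 of 14 for small proline-rich genes with 1 higher, 11 of 15 for basement membrane genes with 1 higher and 18 of 22 for immediate early genes with 1 higher. Mean marker scores per library differed between the days past an exact permutation test with Benjamini-Hochberg adjustment (adjusted p = 0.0413, the lowest that was reached) for 10 of 52 lists. Among these were melanocyte (1.23 higher on P3), macrophage (0.62), proliferation (0.53), embryonic muscle (-1.37) and slow muscle (-1.09). Beside the 3581 calls 6645 genes had an unadjusted p under 0.05. The count was 1764, 1984 and 1629 without WT replicates 1, 2 and 3 of P0, 5570 with the block term, and 6786 with it and without WT replicate 4. It was 6420 in block A, 486 in block B, and 3 with litter as a fixed term, where 2 residual degrees of freedom were left.

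**Figure D4:**
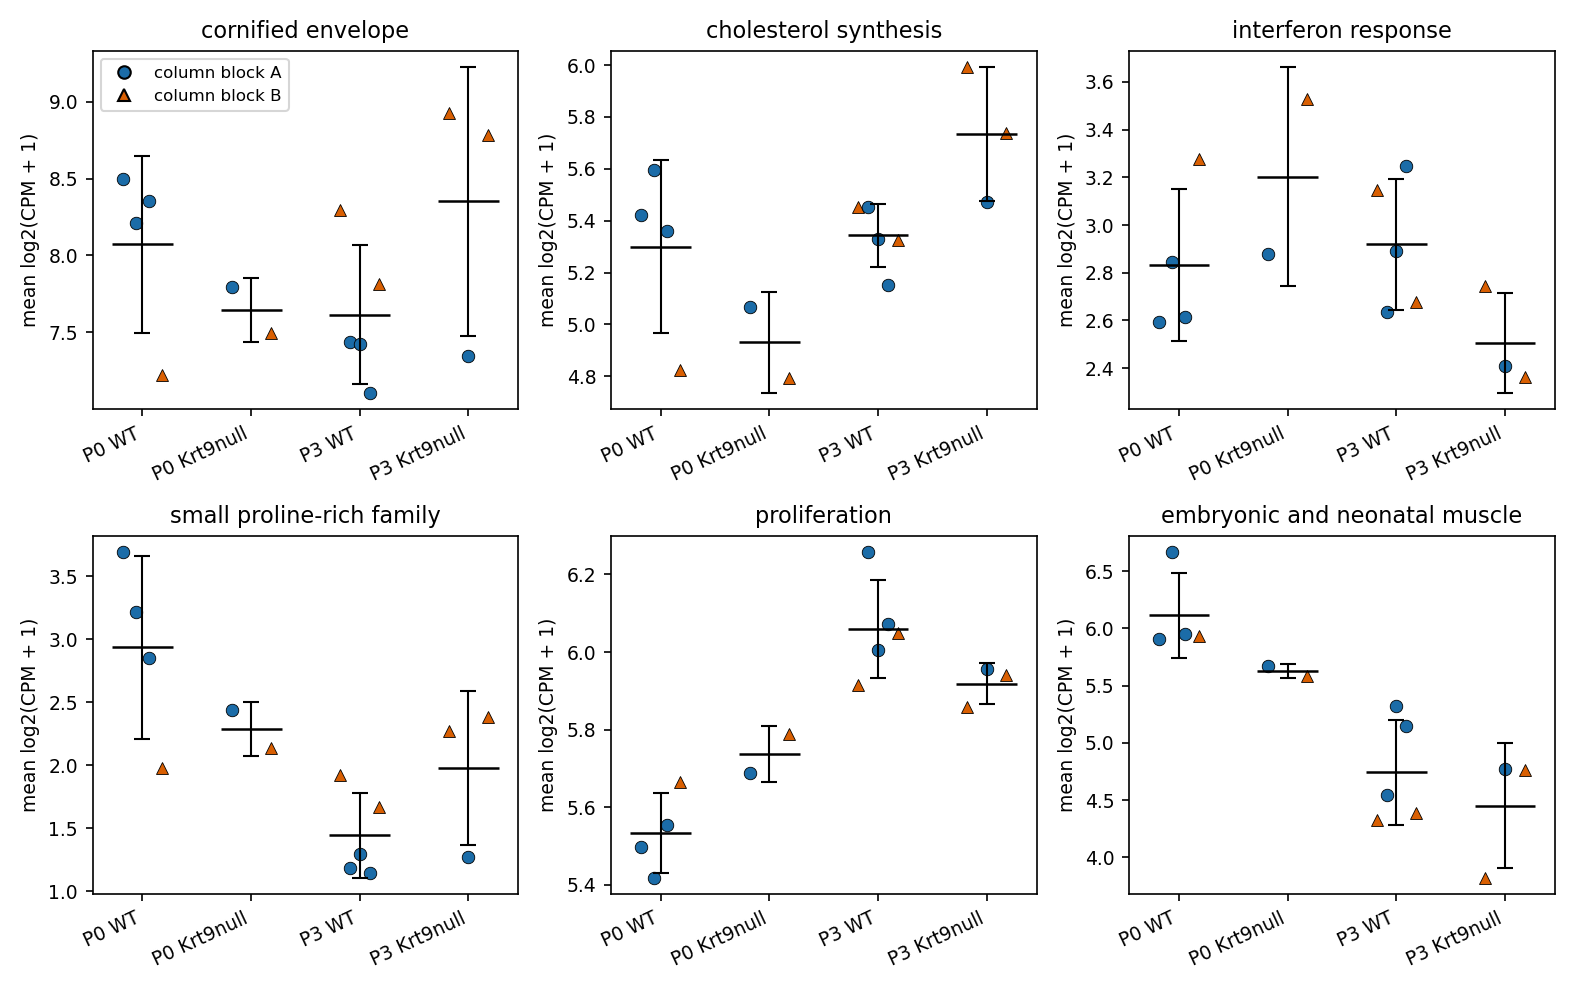
Mean log2(CPM + 1) of 6 gene lists (y axes) in each library by group, with lines and bars for mean and SD and color and shape for the column block. Proliferation scores are higher on P3 than on P0 in WT paws by 0.53 and embryonic muscle scores lower by 1.37 on average, while the 2 genotypes overlap in the cornified envelope on both days.

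In Krt9 null paws (3 of P3 against 2 of P0), 166 genes changed, 73 higher and 93 lower. Krt2, a keratin of the upper epidermis, rose 54.7-fold from 4.37 ± 1.41 to 235 ± 150 CPM (SD, n = 2 and 3; log2 5.77, SE 0.55, edgeR's adjusted p = 0.00446). The differentiation keratins Krt24 (4.05-fold) and Krt79 (2.60-fold) rose with it, 3 of 9 in that list. Melanocyte genes rose in 3 of 9 (Tyr 3.09-fold, Tyrp1 9.67-fold and Oca2 from 0.0413 ± 0.0228 to 1.72 ± 0.813 CPM), and cholesterol synthesis in 4 of 20, with Dhcr7 2.37-fold, Mvd 2.04-fold and Cyp51 2.36-fold higher. Endothelial genes fell in 4 of 16, with Pecam1 from 199 ± 6.67 to 99.4 ± 27.4 CPM, Ramp2 at log2 -0.91 and Esam at 0.501 of its P0 level. Mast cell genes fell in 2 of 12, the histamine-forming Hdc (166 ± 137 to 21.4 ± 9.48 CPM) and the tryptase Tpsab1 (35.9 ± 24.0 to 6.94 ± 2.16 CPM). Embryonic muscle genes fell in 3 of 14 (Tnnt2, Myl4 and Mymx, at log2 -1.45, -1.51 and -2.02). Adjusted over the list alone the counts were 6 of 9, 7 of 9, 16 of 20, 13 of 16, 6 of 12 and 10 of 14, in the order of these lists. Camera called all 6, with adjusted p between 1.07e-18 (cholesterol synthesis) and 8.59e-09 (melanocyte), against adjusted p = 0.134 for differentiation keratins and 0.190 for the other 5 with an estimated correlation. In block A the medians were 0.00 for differentiation keratins, 1.56 for melanocyte, 0.43 for cholesterol, -0.40 for endothelial, -0.83 for mast cell and -1.04 for embryonic muscle genes, and in block B 1.79, 1.36, 1.2, -0.82, -1.01 and -1.48.

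The named rises in Krt9 null paws were completed by Cd300ld (6.08-fold), Gabrp (5.64-fold), the amino acid transporter Slc6a19 (5.54-fold), Tmem56 (5.34-fold), the carbonic anhydrase Car6 (5.26-fold) and Sec14l4 (4.75-fold). The named falls were Calca (81.4-fold lower, 14.8 ± 10.8 to 0.192 ± 0.236 CPM, SD, n = 2 and 3), Fam107a (14.1-fold), Olfr920 (8.71-fold), Hdc (7.60-fold), Ankrd1 (6.52-fold), Zbtb16 (6.16-fold), Angptl7 (5.55-fold) and Nptx1 (5.53-fold lower). All 16 with Krt2 and Tyrp1 had edgeR's adjusted p of at most 0.0493 (Nptx1). In blocks A and B alone log2 fold changes were 4.63 and 6.42 for Krt2, -5.80 and -6.70 for Calca, -2.11 and -3.44 for Hdc, and 0.50 and 3.33 for Slc6a19. Without Krt9 null replicate 2 of P0, where none of these genes was called, Olfr920 had -1.02 and Zbtb16 -1.52, from -3.12 and -2.62. Tyrp1, at log2 3.27, had 2.32 there and 5.06 without Krt9 null replicate 1 of P0, and its call ended in 10 of the 14 fits without 1 library. Krt9 itself had a log2 fold change of 1.37 (SE 0.61, edgeR's adjusted p = 0.300; 0.39 in block A and 1.79 in block B). Beside the 166 calls 3435 genes had an unadjusted p under 0.05. The count was 0 without Krt9 null replicate 2 of P0, 2, 645 and 67 without Krt9 null replicates 1, 2 and 3 of P3. It was 81 without WT replicate 1 of P0, 78 and 83 without WT replicates 2 and 4 of P3, 1070 with the block term and 1805 with it and without WT replicate 4 of P0. It was 13 in block A, 1686 in block B and 1094 by DESeq2.

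The day changes of both genotypes ran together across genes (Pearson 0.57, Spearman 0.45 over 21619 genes, which are not independent replicates). Of the 166 genes called in Krt9 null paws, 47 were called higher and 83 called lower in both genotypes, against 6.20 and 7.51 expected by chance. Only 1 gene was called in opposite directions. By direction alone, whether called in WT or not, 157 of the 166 (94.6%) went the same way in WT paws. Of the 3581 genes called in WT, 88.9% had the same direction in Krt9 null paws. The genotype effects of P0 and P3 had a Pearson correlation of -0.04 and a Spearman correlation of -0.06 across the same genes, with Krt19 the 1 gene called on both days. No marker score passed between the genotypes. On P0 the 15 splits allow no exact permutation p under 0.0667. On P3 5 of 52 lists had an unadjusted p under 0.05 (simple epithelial keratins, heat shock, cholesterol synthesis, epidermal transcription factors and osteoclast), but 0 passed after adjustment (lowest adjusted p = 0.310, exact permutation).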

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

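The tests of explanations, the splits of the libraries and the comparisons of column blocks in this part were chosen only after the result was seen, while the interaction tests were planned. In the WT groups of P0 and P3, with 4 and 5 libraries, 47 measures each gave 94 comparisons, of which 8 held a library far from the others. Chance gives 4.70 at about 1 in 20, but the measures are related to each other, so the comparisons are not independent. In WT paws of P0, replicate 4 stood apart in log2(CPM + 1) of Krt5, at 11.05 (others 11.85 to 11.94), and of Krt6a, at 5.45 (others 8.40 to 8.80). Replicate 4 also stood apart in the scores of barrier lipids, at 5.01 (5.90 to 6.02), immediate early genes, at 4.66 (5.72 to 5.91), and mast cells, at 6.22 (5.15 to 5.33). Replicate 3 of that group had 9.98 for Krt15 (9.58 to 9.62), and replicate 2 had a score of 6.67 for embryonic and neonatal muscle (5.91 to 5.95). In WT paws of P3, replicate 2 had 4.26 for Krt16 (5.87 to 6.31).

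In 20 lists the genotype effect differed between the days by camera's test of the interaction, with the preset correlation, while 0 passed with an estimated correlation. The median of P3 effect minus P0 effect was 2.83 for the small proline-rich family, 1.49 for barrier lipids, 1.48 for the cornified envelope, 1.38 for differentiation keratins, 1.22 for the late cornified envelope family and 1.16 for desmosomes. It was 0.93 for cholesterol synthesis, 0.78 for alarmins and antimicrobial peptides, 0.71 for epidermal transcription factors, 0.60 for epithelial content, 0.58 for immediate early genes, 0.43 for mature fast muscle, 0.39 for glycolysis, 0.38 for the oxidative stress response, 0.37 for the circadian clock and 0.20 for heat shock. Negative medians were -1.16 for the interferon response, -0.42 for endothelial genes, -0.34 for proliferation and -0.33 for limb and distal patterning.

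The first pattern is Krt19, which was higher in every Krt9 null paw than in every WT paw on both days. Krt9 reads counted as Krt19 are argued against, since the lowest Krt19 level of Krt9 null paws on P0 was 13.1 times the highest Krt9 level of WT paws that day, but for P3 alone, where that ratio was 0.589, they stay open. Simple epithelial cells are argued against by Krt8 and Krt18, which accounted for at most 1.69% of the rise of Krt19 in CPM, although Krt7 lay 16.5 CPM higher on P3, 24.1% of that rise, and -0.0325 CPM apart on P0. A response in proportion to the loss of Krt9 RNA is argued against by P0, where the smallest rise of Krt19 was 7.36 times what the P3 rise per CPM of Krt9 lost gives if all Krt9 of the highest WT library were lost (2.22 times with both P3 values moved by 2 SE). An effect of the Krt9 allele, whose type the labels do not give, on the neighbouring gene was not tested and stays open, as does a change that follows from a loss of Krt9 protein, which was not measured.

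The second pattern is the epidermal differentiation genes, with lower medians on P0 and higher ones on P3 in Krt9 null paws, called by camera with the preset correlation and not with an estimated one (adjusted p = 0.246 for the cornified envelope interaction). The column block as the whole cause is argued against by the cornified envelope score per library, which with a block term within each day had an interaction of 0.85 (SE 0.31) and a P3 difference of 0.56 (SE 0.20), and 1 library as the cause of the interaction by the lowest median of 1.11 over the 14 left-out libraries. That score fit takes the genotype effect as equal in both blocks. On P3 the 1 Krt9 null library of block A scored 7.35, within the 7.11 to 7.44 of the WT libraries of that block, so the P3 difference was not seen there. A change in the share of whole epidermis stays open beside a shift toward differentiated layers. Basal keratins had a median interaction of 0.41 beside 1.48 for the envelope list. The interaction of the score difference of the 2 lists was 1.07 (SE 0.60) without a block term, less than 2 SE from 0. It was 1.11 (SE 0.43) with the block term and 0.79 (SE 0.32) with one within each day, both more than 2 SE from 0. However, the epithelial score as a covariate took the envelope median to -0.17 and ended its call. On P0 the genotype difference of the envelope score was -0.29 (SE 0.23) with a block term within each day and -0.43 (SE 0.46) without one. Both lay within 2 SE of 0, so the scores show no clear P0 difference to assign to block or genotype. A part from the block stays open on P3 and for the interaction, whose scores shrank from 0.87 and 1.30. A change in the timing of differentiation in Krt9 null paws may be considered as a hypothesis for the interaction only, and litter, the block, the share of epidermis and the few P0 Krt9 null libraries stay open beside it.

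The third pattern is the column block. GC content as its whole cause is argued against by the 2857 of 5017 block genes that stayed past the threshold with a GC offset, although the median size of the difference over all 5017 dropped from 0.44 to 0.33. The ratio of Col1a1 to Col1a2, transcripts of the same cells, had a gap of 0.25 in log2 between the blocks. It was picked after its values were seen and is a measure by which the blocks were described. It therefore cannot test tissue make-up as the cause, which stays open. A difference in library preparation or sequencing stays open, as the labels give no batch. No other biological explanation was tested.

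For the genes called between genotypes on P3, 5 of the 56 splits of the 8 libraries gave as many calls as the real 1, so chance was not excluded for the count, and the highest other split gave 2412. That split set WT replicate 1 and Krt9 null replicates 1 and 3 against the rest, which points to a structure of the samples. These 3 libraries are of block B, but so is WT replicate 5 on the other side, and they also had the highest cornified envelope scores of P3 (8.29, 8.93 and 8.78, others 7.11 to 7.82). The next splits, with 2159 and 1478 calls, also drew their 3 libraries from 1 block, and with the block term the real count was 7. For the day comparison in WT, 1 of 100 splits, the real one, gave as many as 3581, with 853 as the highest other, so chance was excluded. For the averaged genotype effect, 3 of 100 splits, with the real one among them, gave as many as the real 2. The others gave 14 and 686 calls and both set these 3 libraries of P3 apart, which points to the same structure. The second of the real calls, Spp1, also ended in most fits without 1 library. The test therefore does not exclude chance for so small a count. With the block term the real count was 2.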

How the results depend on the processing

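The alternatives with the column block, also within each day, the GC offset and the removal of WT replicate 4 of P0 together with the block were chosen after seeing the data, and the others were planned. Of the genes chosen by the rule for single genes and run under the alternatives, none that was called reversed its direction. The cause of a moved value was not tested, except where fewer libraries or residual degrees of freedom set it, as with 1 block alone or litter as a fixed term with 2 residual degrees of freedom. Depth limits which genes could be tested, as 21619 of the 36822 genes with any count passed the filter. Counts below are in the order genotype on P0 (1 gene called), genotype on P3 (1), day in WT (3581), day in Krt9 null paws (166), interaction (0) and averaged genotype effect (2), and contrasts left out stayed within 1.5 times.

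With no low-count filter, 182, 631, 1692, 617 and 203 genes were called (all but day in WT), and Krt9 on P3 was called at -1.88. That call had edgeR's adjusted p = 2.84e-19, against 0.694 in the main fit at nearly the same log2 fold change. The p-values of the unfiltered fit are therefore not comparable with those of the main fit, and its counts and the Krt9 call carry little weight. DESeq2 called 9, 26, 1094 and 85 (P0, P3, day in Krt9 null, interaction) and Krt9 on P3 at -1.86. The replicate block of litters as a fixed term gave 0 on P0, 0 on P3, 3 for day in WT, 0 for day in Krt9 null paws and 0 for the average, and turned the P0 median of mature fast muscle to 0.071. The replicate block of litters within a day as a random term gave 2 on P0 and 3 for the interaction. The column block as a term gave 7, 5570, 1070 and 7 (P3, both day contrasts, interaction), within each day 2, 39, 6027, 98 and 44 (all but the average), and without WT replicate 4 of P0 as well 1251, 55, 6786, 1805, 1491 and 7 over all 6. The last fit left block B no WT library on P0, so its P0 and interaction counts rest on a block effect taken as equal on both days. Block A alone gave 627, 6420, 13, 26 and 12 (all but P3), and block B alone 9, 112, 486, 1686, 14 and 4. Block B alone turned the P0 medians of the cornified envelope to 0.29 and of barrier lipids to 0.26, and the WT day median of immediate early genes to 0.18. Day in Krt9 null paws gave 41 without sex, 6 with the epithelial score, 1 with only the groups compared and 314 with the GC offset. The interaction gave 1 with library size only. The average gave 1 with library size only, with the filter of 1 CPM in 4 libraries, without sex and with the litter 2 males summed. Library size only moved the median of all genes by 0.11 in day in WT, 0.11 on P0 and -0.16 in the interaction, and 69.1% of the WT day calls were then higher, against 51.3%.

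Of the lists called by camera (26, 26, 25, 30, 20 and 21), an estimated correlation left 1, 1, 0, 0, 0 and 1, and fry called 1, 1, 15, 5, 0 and 1. The epithelial score left 17 on P0, 11 on P3 and 10 for the interaction. It turned the P3 medians of the cornified envelope to -0.11, of the late cornified envelope family to -0.12 and of barrier lipids to -0.076. The interaction median of epithelial content was -0.12 with it, which is no test, as the score is the mean of that list. Block A alone left 11 on P3, and for the average the replicate block of litters within a day left 11 and the column block term 13. The window of 20 Mb around Krt9 gave Fisher's exact p = 0.0673 for the average, against 0.0399, but both rest on the call of Krt19 alone and say nothing about other genes.

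Leaving out 1 library gave between 1 and 3 genes for genotype on P0 (3 without WT replicate 4 of P0), between 1 and 200 on P3 (200 without Krt9 null replicate 2), between 1629 and 4332 for day in WT, between 0 and 645 for day in Krt9 null paws, between 0 and 47 for the interaction and between 1 and 3 for the average. The list calls ran from 14 to 32, 23 to 30, 25 to 28, 25 to 34, 17 to 28 and 12 to 23, lowest without Krt9 null replicate 2 of P0 (14) on that day and without Krt9 null replicate 1 or 3 of P3 (12) in the average. The P3 difference of Krt9 ran from -2.54 to -1.57. Where a left-out library left 1 Krt9 null library on P0, it was assumed to vary like the other groups. Of single genes and lists, 126 values lost and 9 gained their call under a left-out library, and 229 lost and 59 gained it under the other alternatives, while 1657 and 2375 stayed on their side.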

Other observations

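Marker genes of further cell types and a set of target genes were compared between P0 and P3 in WT paws. Of 13 erythroid genes 6 rose and none fell over all genes, with a median log2 fold change of 2.90 and 7 higher when adjusted over the list alone (camera adjusted p = 0.000526, adjusted p = 0.545 with an estimated correlation). Neutrophil genes rose in 6 of 15 (median 1.54, 9 higher adjusted over the list alone, camera adjusted p = 3.97e-07, adjusted p = 0.395 with an estimated correlation). Of 16 lymphocyte and Langerhans cell genes 9 rose and 1 fell (median 1.32, the same counts adjusted over the list alone, camera adjusted p = 0.000429, adjusted p = 0.312 with an estimated correlation). Targets of the mechanosensitive factors YAP and TAZ fell in 11 of 20 (median -0.44, 11 lower adjusted over the list alone, camera adjusted p = 8.68e-07, adjusted p = 0.300 with an estimated correlation). In blocks A and B alone the medians were 2.80 and 2.71 for erythroid, 1.45 and 1.72 for neutrophil, 1.48 and 0.64 for lymphocyte and Langerhans cell genes, and -0.40 and -0.28 for YAP and TAZ targets. Sweat gland, nerve and Schwann cell and Merkel cell genes had medians of 0.06, 0.14 and 0.84 and were not called by camera (adjusted p = 0.846, 0.263 and 0.0617).

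The column block added a tier of genotype differences to P3, chosen after seeing the data. Tmem79, which encodes a membrane protein of the lamellar granule system, was at 12.3 ± 2.38 CPM in WT and 21.5 ± 4.95 CPM in Krt9 null paws of P3 (SD, n = 5 and 3), with a log2 fold change of 1.02 (SE 0.17, edgeR's adjusted p = 0.0452) with the block term and 0.98 (edgeR's adjusted p = 0.361) without it. The heat shock gene Hspa1a was at 17.7 ± 2.20 and 28.7 ± 5.84 CPM, with 0.78 (SE 0.12, edgeR's adjusted p = 0.0452) and 0.79 (edgeR's adjusted p = 0.227). Tmem79 had 0.40 in block A and 1.01 in block B, and Hspa1a 0.37 and 0.83.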
